A study of Oncorhynchus mykiss with 24 samples.

How the data were processed

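Transcript levels were measured in liver, kidney and gill of rainbow trout (Oncorhynchus mykiss) from the strains BORN and TCO with 24 one-colour microarrays. The groups were the 12 combinations of tissue, strain and water temperature, with 2 arrays each. Per the labels, each array carried Cy3-labelled RNA pooled from 5 fish. The labels do not say whether the pools of a group held different fish, or whether the tissues came from the same fish, so the p-values measure only the spread between these samples, which may be technical.

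The deposited scanner files hold spot intensity on a linear scale, and per the file headers they were made with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed spatial trends within each array but did not normalise between arrays. The array design carries Atlantic salmon (Salmo salar) sequences, so trout RNA was measured on probes of a related species. The authors also deposited 6 tables of probes, each for a tissue and strain, that compare 0 °C with 5 °C. Per the file headers, the authors' deposited tables give log2 fold changes, p-values with adjusted p-values, and test statistics (a t and a B score). The normalisation and model behind those tables are not given in the sources used here.

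Each array held 62976 spots, of which 61657 were no control spots. They belonged to 49255 probes, so 12402 were repeats. Between 32.8% and 52.2% of probes were well above background on an array, according to the scanner software's own call, and this share limits which genes could be compared. Outlier spots were left out and the remaining spots of a probe were averaged. The processed signal was taken to log2, and the 75th percentile over the 12385 probes well above background on all 24 arrays was subtracted from each array.

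Gene names came from the array's own gene and protein name columns, which can be old. Of the 49255 probes 13841 carried a name, with 8366 distinct labels, and 35414 did not. None of the probes' accessions matched the trout gene table used here (0 probes), while 832 of the 3465 distinct symbols occurred in it. Symbols that lists needed were also read from protein names. Where a gene had several probes, the probe with the highest mean level in the tissue stood for it in the lists, and disagreements between probes are given beside the gene. Labels that name no gene were left out of the text.

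Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. All 24 arrays entered 1 fit with a mean per group, which left 12 residual degrees of freedom, because 1 tissue alone leaves 4. A probe was tested in a tissue if it was well above background on both arrays of at least 1 of the tissue's 4 groups. The Benjamini-Hochberg method adjusted p over the tested probes of each comparison, and an adjusted p under 0.05 is called past the threshold. The 18 comparisons were the difference between 0 °C and 5 °C averaged over both strains, the same difference in each strain, its difference between strains, the difference between strains averaged over temperatures, and the difference of the temperature effect between tissues. Changes are log2 differences with the standard error (SE) of the fit. Where every array of a group was not well above background, only a bound is given. This bound sets the mean of the brighter group against a mean of the dimmer group, after normalisation. For the latter, each array counts with the probe's own signal, or with the lowest signal among probes well above background if that is higher. Where the own signal was higher on each array, the bound equals the fitted change. A probe above that lowest signal may still not be well above background. The bounds carry no margin for error, so they are not strict limits.

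The groups, comparisons, tests, 38 gene lists and the rule for named genes were fixed before the data were examined, with some exceptions. The tests of the lists between strains and the alternatives named below as chosen later were added afterwards. The tests of the dim arrays and of shared pools name features of these data, so they followed a first look at them. For genes picked by size of change, the rule for named genes asked that the compared arrays did not overlap within a strain or temperature. Among those past the threshold, it took up to 10 named genes per direction with the largest change for both strains together. It took up to 5 per direction for a single strain, up to 8 per direction for the strain difference, up to 4 members per list with the lowest p, and 21 genes of cold, heat and stress responses whatever their result. Where fewer than 5 named genes per direction passed, up to 5 with the lowest p are given as values that did not pass. From each of the authors' deposited tables it took up to 4 per direction.

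Gene lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. Counts adjusted over the list alone are given beside those over all probes. The scripts were tested on simulated data drawn from the real arrays' levels, with known changes in some probes. For both strains together in liver, 54% of probes changed by 1 on the log2 scale and 98% of those changed by 2 were recovered. In BORN alone these shares were 12% and 86% in liver, 4% and 88% in kidney, and 10% and 76% in gill. The simulated noise was independent for each probe and held no deviations of whole arrays, such as those of dim arrays. The shares may therefore overstate what is recovered from the real arrays.

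Alternatives were quantile normalisation, normexp background correction with an offset of 50, other filters on dim probes, 1 probe per gene, a fit per tissue, the replicate number or the slide as a block, an unadjusted p with a 2-fold change, and leaving out each array in turn. The arrays lay on 6 slides scanned on 3 days, and 0 slides were scanned on more than 1 day, so the slide block also covers the day. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9 and the R package data.table, version 1.17.8. Results for 2 genes of the kidney comparison of strains are not reported here.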

Results

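The data describe how gene expression in 3 tissues of rainbow trout differed after 30 min in water cooled to 0 °C from that after 30 min in water at the ambient 5 °C. The fish were 8 months old and belonged to the strains BORN, which held both sexes, and TCO, which was female, so that strain and sex cannot be told apart. Each of the 12 groups had 2 arrays, each of RNA pooled from 5 fish. The median processed signal per array was 4.34 to 6.06 in liver, 7.34 to 15.9 in kidney and 5.14 to 15.8 in gill. Arrays of the same group correlated at r = 0.949 to 0.992 across probes, which are not independent replicates. Both the gill BORN 5 °C replicate 2, with a median signal of 5.14, and the kidney TCO 5 °C replicate 1, with 7.34, were dim for their tissue. The number of arrays limits the precision of every value below.

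The first question was which liver transcripts differed between 0 °C and 5 °C in both strains. HMOX1, which codes for the haem-degrading enzyme haem oxygenase, rose by 1.78 ± 0.315 (log2, SE, 4 arrays against 4; adjusted p 0.0149). Heparin-binding growth factor 1 rose by 2.52 ± 0.518 (adjusted p 0.0286), and 1 of 2 TCO arrays at 5 °C measured it. ANGPTL4, an inhibitor of lipoprotein lipase, rose 2.84-fold (adjusted p 0.0343) and sclerostin domain-containing protein 1 (SOSD1) by 1.63 (adjusted p 0.00378). HSPA5, the endoplasmic reticulum chaperone also called glucose-regulated protein 78, fell by 1.13 on the log2 scale (adjusted p 0.0198), although another HSPA5 probe gave -0.48 (adjusted p 0.510). GCLM, a subunit of the enzyme that starts glutathione synthesis, fell by 1.33 on the log2 scale (adjusted p 0.0173).

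Of 18315 tested liver probes 318 passed the threshold, 175 higher and 143 lower at 0 °C. Among the others that rose were C-type natriuretic peptide 1 (1.53) and secretagogin (1.51), with some 5 °C arrays below background for both (natriuretic peptide measured on 1 of 2 in TCO, secretagogin on 1 of 2 in each strain). FMR1, a translational regulator, was at least 3.09-fold higher, PR285, a transcriptional coactivator, at least 2.76-fold higher, and GSK-3-binding protein at least 2.53-fold higher. DDIT4L, an inhibitor of mTOR signalling, fell by 2.07 on the log2 scale (adjusted p 0.0299), with 1 of 2 TCO arrays measured at each temperature. S-adenosylmethionine synthetase fell by 1.52 on the log2 scale, and HNRNPQ changed by -1.31 (adjusted p 0.00353). The translation release factor ERF3B changed by -1.05 (adjusted p 0.0122) and RAB8A by -1.06, with 1 of 2 arrays measured at 0 °C in each strain for RAB8A. SH2 domain-containing protein 2A was at least 3.45-fold lower, RANB3 at least 2.64-fold lower and the histone acetyltransferase MYST1 at least 2.12-fold lower. For each of these genes all 4 differences between arrays of the same replicate number had the same sign, and these arrays shared a slide. The rule for named genes asked for at least this, so the shared sign adds no support. Of all 318 probes, 287 had no overlap between the 0 °C and 5 °C arrays of either strain.

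None of the tested genes among 21 of cold, heat and stress responses passed the threshold in liver, apart from the HSPA5 probe above. The values that did not pass were -0.16 for the cold-inducible RNA-binding protein CIRBP (adjusted p 0.552), 0.29 for HSPA1A, -0.67 for HSP70, 0.11 for HSPA8, -0.35 for HSP90AA1, 0.10 for HSP90AB1 and -0.61 for the collagen chaperone SERPINH1. The immediate early genes FOS, JUNB and IER2 gave -0.39, 0.02 and 0.70, and IER2 had an adjusted p of 0.107. The glucocorticoid-responsive genes PER1 and TSC22D3 gave 0.13 and -0.24, FKBP5 is given no value because a group was below background (adjusted p 0.958), and the metabolic enzymes PCK1 and SCD gave -0.19 and -0.30. In kidney these genes ranged from -0.56 for IER2 to 0.21 for PCK1, with -0.06 for CIRBP, and in gill from -0.58 for TSC22D3 to 0.55 for HSP70, with -0.11 for CIRBP, again without passing.

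Of 32 lists tested in liver with camera, 6 passed the threshold, and 0 did with an estimated correlation or with fry's directional test. The unfolded protein response list of 10 genes went down as a list (median -0.38, adjusted p 0.0435; p = 0.109 with an estimated correlation), with 8 genes lower. None passed the threshold and 1 did adjusted over the list alone, and HYOU1 gave -0.73 and ASNS -0.69. The list of splicing factors and hnRNPs (30 genes) went down by a median of -0.14 (adjusted p 0.0213; p = 0.0620 with an estimated correlation). Of its genes 1 fell, SNRPD1 at -0.53, 29 did not pass and 5 passed adjusted over the list alone. The 67 ribosomal protein genes had a median of -0.18 with 58 lower and 0 past the threshold on their own or adjusted over the list alone (adjusted p 0.0208; p = 0.540 with an estimated correlation). Granulocyte and macrophage markers (14 genes) went up by a median of 0.31 (adjusted p 0.0208; p = 0.0940 with an estimated correlation). Of them 1 rose, CD209 at 1.11, with 13 not past the threshold and 1 adjusted over the list alone. Lymphocyte markers (10 genes, 9 higher) had a median of 0.45 (adjusted p 0.0213; p = 0.198 with an estimated correlation). Interferon-stimulated genes (17 genes, 15 higher) had a median of 0.32 (adjusted p 0.0370; p = 0.245 with an estimated correlation). In both lists 0 genes passed the threshold, also adjusted over the list alone, and ISG15 gave 1.72.

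Among lists that did not pass, antioxidant and glutathione enzymes (26 genes) held 1 that rose, HMOX1, 1 that fell, GCLM, and 24 that did not pass, with 2 adjusted over the list alone. Of 11 glucocorticoid-responsive genes 1 rose, ANGPTL4, and 6 passed adjusted over the list alone, and G6PC gave 1.28. Of 21 heat shock proteins and chaperones 0 passed and 1 did adjusted over the list alone, HSPA4 at -1.11 (adjusted p 0.0616). Of 18 immediate early genes 0 passed and 5 did adjusted over the list alone, with 0.82 for CTGF and 0.69 for CEBPD. Digestive enzyme genes of the pancreas stood apart on 2 liver arrays: their list median lay 4.30 above the liver mean on the BORN 5 °C replicate 1 and 4.50 above it on the TCO 0 °C replicate 1, against -2.02 to -0.69 on the other liver arrays. Without both arrays 165 liver probes passed the threshold, 93 of them among the 318, and the calls of the ribosomal and interferon lists ended. All 6 list calls in liver ended without the BORN 5 °C replicate 2 and with normexp.

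The liver count moved with single arrays and with the model. It was 92 without the BORN 0 °C replicate 1, 94 without the TCO 0 °C replicate 2, 156 without the TCO 0 °C replicate 1, 189 and 196 without the BORN 5 °C replicates 1 and 2, 194 without the TCO 5 °C replicate 1. It was 34 with normexp, 766 with slide as a block, and 0 in a limma fit to the 8 liver arrays alone, where 2434 probes had an unadjusted p under 0.05.

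Within BORN liver, 17 probes passed the threshold, 13 higher and 4 lower at 0 °C. Ubiquitin-conjugating enzyme E2 A was at least 5.85-fold higher, the liver-expressed antimicrobial peptide LEAP2 at least 2.78-fold and prepro-cathepsin C at least 2.57-fold. The membrane protein M4A15 rose by 1.87 (adjusted p 0.0362), and RANB3 was at least 4.04-fold lower. Within TCO liver, 77 probes passed, 40 higher and 37 lower. There HMOX1 rose by 2.45 (adjusted p 0.0337), KCTD7 by 3.53 with 1 of 2 arrays measured at 5 °C. GSK-3-binding protein was at least 4.16-fold higher, ICT1 at least 3.79-fold higher and FMR1 at least 3.37-fold higher. Carbonyl reductase 1, which reduces ketones on steroids and other compounds, changed by -4.56 (adjusted p 0.0145) and profilin-2 by -3.62 (adjusted p 0.0374), each with 1 of 2 arrays measured at 0 °C. Mitochondrial arginase-2 was at least 3.51-fold lower and ACTR2 at least 2.86-fold lower. Of the 17 BORN probes 13 had the same direction in TCO and 1 passed there, and of the 77 TCO probes 63 had the same direction in BORN. The test of the difference between strains passed for 1 liver probe, with 1193 at an unadjusted p under 0.05. Leaving out the BORN 5 °C replicate 2 gave 160 probes in BORN and leaving out the BORN 0 °C replicate 2 gave 124, with 36 without the BORN 5 °C replicate 1, 67 without either TCO 5 °C array and 31 without either TCO 0 °C array. In TCO the count was 50 without either BORN 5 °C array, 198 (160 higher and 38 lower) without the TCO 5 °C replicate 2, 36 without the TCO 5 °C replicate 1 and 13 without the TCO 0 °C replicate 2. Without both arrays high in pancreatic genes it was 112 (40 higher and 72 lower), 36 of them among the 77.

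In kidney no probe passed in both strains together (0 of 24717 with limma, 918 at an unadjusted p under 0.05). The lowest p among named genes higher at 0 °C belonged to a collagen alpha-3 homolog (at least 2.17-fold), cellular retinoic acid-binding protein (1.83, adjusted p 0.159), the collagen gene COL1A1 (0.91; its other probes gave -0.40 to 0.38), the matrix protein mimecan (at least 2.91-fold) and nucleolar RNA helicase 2 (at least 2.03-fold). Among those lower were PHLA2 (-0.90), the T cell receptor gene TRAC (-0.87), LASP1 (-0.71) and the plasma protein gene APOH (-1.20). In BORN, 5 kidney probes passed, all higher at 0 °C (427 at an unadjusted p under 0.05), among them genes of muscle fibres. The calcium buffer gene PVALB2 was at least 9.40-fold higher (adjusted p 0.0110), and myosin light polypeptide 3-1 rose by 3.24 (adjusted p 0.0110). A fast muscle tropomyosin probe of TPM1 rose by 3.11 (adjusted p 0.0338; another TPM1 probe gave -0.10), and the collagen alpha-3 homolog was at least 3.15-fold higher. In TCO, 1 kidney probe passed, carbonyl reductase 1 at -6.02 ± 0.630 (adjusted p 0.00215). No kidney probe passed the test between strains (0 with limma, 546 at an unadjusted p under 0.05). The BORN count was 11 without the BORN 5 °C replicate 1 and 0 without any of the other 3 BORN kidney arrays. The TCO count was 7 and 16 without the TCO 5 °C replicates 1 and 2 and 2 without either TCO 0 °C array.

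The skeletal muscle list changed differently in the strains in kidney, but its level also differed between arrays of a TCO group. Over both strains its 14 genes had a median of 1.07 with 12 higher (adjusted p 4.89e-08; p = 0.00288 with an estimated correlation, which did not pass once adjusted, at 0.0980). It had 0 past the threshold and 6 adjusted over the list alone. In BORN 11 of 14 were higher with a median of 1.75, 1 passed (PVALB2) and 7 passed adjusted over the list alone. Its values included 3.63 for MYLPF, 3.34 for TNNT3 and 2.62 for CKM. In TCO 6 of 14 were higher with a median of -0.08. Against the kidney mean the list lay at -0.44 and 0.84 on the TCO 5 °C replicates 1 and 2. It lay at 1.06 and 1.09 on the BORN 0 °C arrays and at -0.59 and -1.14 on the BORN 5 °C arrays. Without the TCO 5 °C replicate 2, 12 of 14 genes were higher at 0 °C in TCO too, with a median of 0.55. The difference between strains over the list, tested after the values were seen, had a median of -1.73 for TCO minus BORN (camera p 7.21e-09, p = 0.00344 with an estimated correlation, fry p 0.00944). Of 34 lists 5 passed in kidney and 0 did with an estimated correlation or with fry's directional test.

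Ribosomal protein genes (68) went down as a list in kidney by a median of -0.26 (65 lower, adjusted p 5.18e-14; p = 0.143 with an estimated correlation), with 0 past the threshold, also adjusted over the list alone. On the dim TCO 5 °C array this list lay 0.60 above the kidney mean, against -0.24 to 0.17 on the others, and the call ended without that array and under quantile normalisation, but not without both dim arrays (adjusted p 0.0154). Oxidative phosphorylation genes (39) went down by a median of -0.14 (30 lower, adjusted p 0.00216; p = 0.220 with an estimated correlation), with 0 past the threshold, and this call also ended without that array and with normexp, but again not without both dim arrays (adjusted p 0.0296). Erythrocyte markers (9) did not pass as a list in kidney (adjusted p 0.120) but did without both dim arrays, where they went down (adjusted p 0.00797), and in TCO 9 of 9 were lower, with a median of -0.52 on all arrays. Hepatocyte markers (17) had a median of -0.32 (14 lower, adjusted p 0.000253; p = 0.103 with an estimated correlation). Of these 0 passed the threshold and 1 did adjusted over the list alone, and ALB gave -1.64 and APOA1 -1.63. The list lay 1.24 above the kidney mean on the BORN 5 °C replicate 1, against -0.83 to 0.56 on the others, and its call ended without that array and without the BORN 0 °C replicate 2. Immediate early genes (18) had a median of -0.12 (12 lower, adjusted p 0.0268; p = 0.131 with an estimated correlation) with 0 past the threshold, and this call ended with slide as a block (adjusted p 0.0865), with normexp and without each of 4 single arrays in turn.

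**Figure D1:**
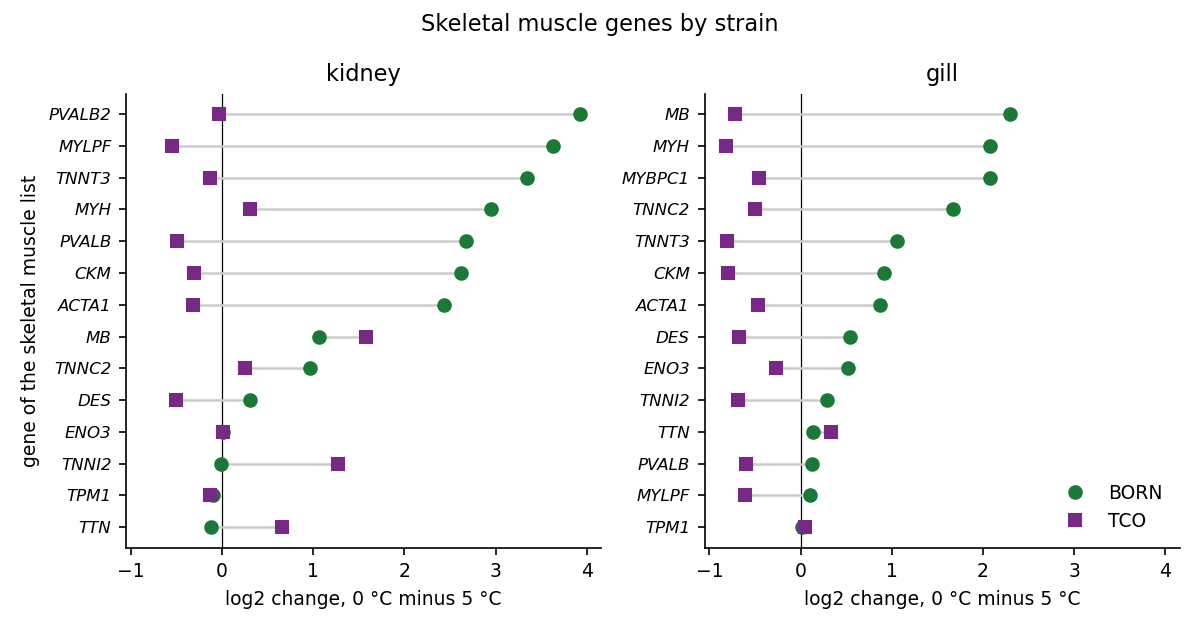
Log2 change between 0 °C and 5 °C of each tested gene of the skeletal muscle list in kidney and gill, as the difference of group means with 2 arrays per group, for BORN and TCO. In kidney the BORN median is 1.75 and the TCO median -0.08, and in gill they are 0.71 and -0.60.

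In gill 2 probes passed in both strains together, both lower at 0 °C (of 24421; 2949 at an unadjusted p under 0.05). The named one was the zinc finger protein gene Rlf, at least 3.50-fold lower (adjusted p 0.00925), with 1 of 2 arrays measured in BORN at each temperature. Catalase gave 0.98 (adjusted p 0.0966), the transcriptional repressor BCL6 1.35, NDRG1 a bound of at least 1.55-fold higher, PICK1 0.69 and a group XIIB phospholipase A2-like gene 0.75, none past the threshold. Lower values that did not pass were those of the respiratory chain gene COX7C (-1.24, adjusted p 0.0527; another COX7C probe gave -0.49), carbonyl reductase 1 (-2.71, adjusted p 0.0550), a probe of MYLPF (-1.74) and cystatin-B (-1.56). In TCO gill 9 probes passed, 2 higher and 7 lower. TSC22 domain family protein 4 was at least 1.92-fold higher and the immunoglobulin gene IGHM at least 3.97-fold higher, whereas GTPase IMAP family member 7 was at least 3.45-fold lower, Rlf at least 4.98-fold lower and carbonyl reductase 1 fell by 4.35 on the log2 scale (adjusted p 0.0261). In BORN gill limma gave 0 probes past the threshold and 4628 at an unadjusted p under 0.05, and no probe passed the test between strains (0, with 2062 unadjusted).

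Without the BORN 5 °C replicate 1, which leaves the dim array as the 5 °C side, 5550 probes passed in BORN gill and 3289 in both strains together. Without the dim array the counts were 0 and 0. With normexp they were 10189 and 1. With slide as a block they were again high, but the BORN 5 °C replicate 1 was the only array on its slide. The block thus sets that array aside and leaves the dim one as the 5 °C side, so it is no separate check. The count for both strains was also 0 without the BORN 0 °C replicate 1, and 1 and 7 without the TCO 0 °C replicates 1 and 2. The TCO count was 0 and 5 without the TCO 5 °C replicates 2 and 1, and 1 without either TCO 0 °C array. Ribosomal protein genes (68) went down as a list by a median of -0.48 (65 lower, adjusted p 1.81e-20; p = 0.0759 with an estimated correlation) with 0 past the threshold. Oxidative phosphorylation genes (39) went down by a median of -0.27 (31 lower, adjusted p 4.32e-05; p = 0.119 with an estimated correlation), also with 0, and this call ended without the dim array and with normexp. On that array the ribosomal list lay 0.91 above the gill mean, against -0.29 to 0.03 on the others. The ribosomal call nevertheless held under 18 of 19 alternatives, those without the dim array included, and ended only with an estimated correlation. In BORN, which holds that array, the ribosomal median was -0.73 and 31 of 68 genes passed adjusted over the list alone. In TCO these values were -0.22 and 0. In each strain 64 of 68 ribosomal genes were lower at 0 °C. The ribosomal and oxidative phosphorylation lists were the 2 of 32 past the threshold in gill, and 0 passed with fry's directional test. Over both strains 0 genes of either passed adjusted over the list alone. The skeletal muscle list did not pass over both strains. Its 14 genes were higher in BORN in 14 of 14 cases, with a median of 0.71, 0 past the threshold and 1 adjusted over the list alone (MB at 2.30). In TCO 12 of 14 were lower, with a median of -0.60.

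Carbonyl reductase 1 was lower at 0 °C in TCO in liver, kidney and gill on the same probe. Its changes of -4.56, -6.02 and -4.35 all passed the threshold, and in each tissue both TCO 5 °C arrays lay above both TCO 0 °C arrays. With slide as a block the liver call held (adjusted p 0.0328) and those in kidney (0.0531) and gill (0.121) ended, and the gill call also ended with the replicate block and without each TCO gill array in turn. With normexp the liver and gill calls ended, at -2.55 and -2.24. In BORN the changes were 0.87, -0.28 and -1.07, none past the threshold. The difference between strains did not pass in any tissue (adjusted p 0.101 in liver, 0.0869 in kidney and 0.589 in gill), so the effect is not shown to differ between them. Another carbonyl reductase 1 probe gave -0.60 in kidney and 0.04 in gill in TCO, and one tested in gill alone gave -0.47 there. In TCO liver the former had an adjusted p of 0.149 and was lower at 0 °C.

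**Figure D2:**
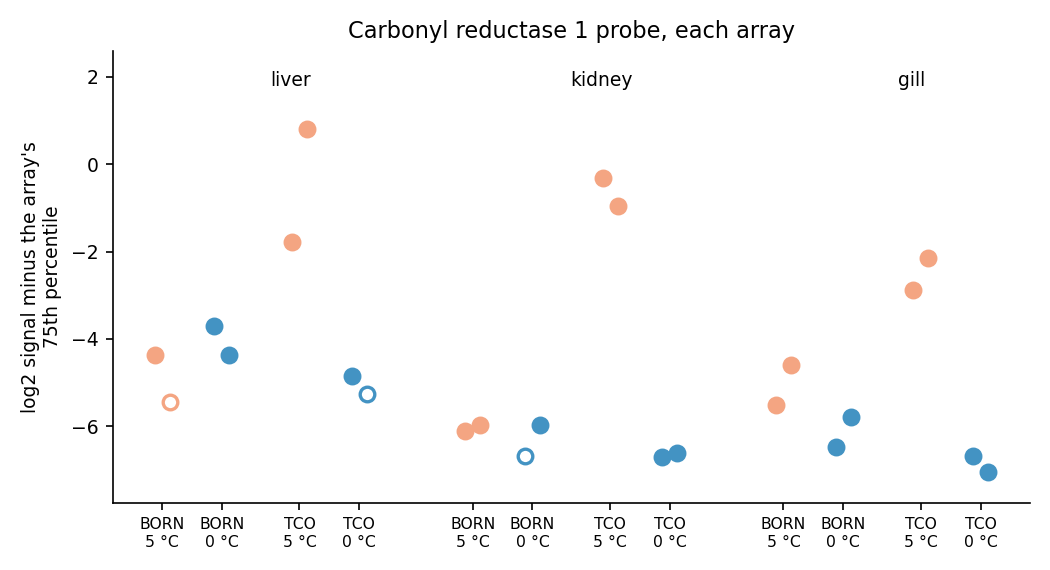
Normalised log2 signal of the carbonyl reductase 1 probe on each of the 24 arrays, by tissue, strain and temperature. In TCO kidney the 5 °C arrays lie at -0.31 and -0.97 and the 0 °C arrays at -6.71 and -6.61.

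No probe passed the test of whether the temperature effect differed between tissues. The counts with limma were 0 of 17579 for liver and kidney, 0 of 17304 for liver and gill, and 0 of 22682 for kidney and gill, with 863, 1130 and 351 at an unadjusted p under 0.05. The genes above are therefore not shown to respond in 1 tissue only.

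The strains differed in many more probes than the temperatures did. The probes carry Atlantic salmon sequences, so these differences may include sequence variants under the probes, which was not tested. Averaged over temperatures, the MHC class I antigen gene was at least 37.7-fold higher in TCO in kidney and at least 117-fold higher in gill, calpain small subunit 1 at least 11.1-fold higher in liver and at least 69.7-fold in kidney, with a change of 5.49 in gill. Galectin-3 was lower in TCO by -3.76 in liver, -3.16 in kidney and -3.36 in gill. In liver 1705 probes passed, 865 higher and 840 lower in TCO. In kidney 860 passed, with 474 higher and 386 lower, and in gill 1065, with 505 higher and 560 lower. Of 17115 probes tested in all 3 tissues, 190 passed in each and 189 of these had the same direction, 114 higher and 75 lower in TCO. Liver and kidney shared 313 probes where independent lists would share 47.6, liver and gill 342 against 67.3, and kidney and gill 337 against 30.2. The gill count was 3932 without the BORN 5 °C replicate 1 and 471 without the BORN 0 °C replicate 1. The lowest counts with an array left out were 1077 in liver (without the TCO 0 °C replicate 2) and 391 in kidney (also without the TCO 0 °C replicate 2).

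In liver, zona pellucida protein X, an egg envelope protein that the liver of female fish makes, was at least 9.90-fold higher in TCO. Ankyrin repeat domain-containing protein 13D was higher by 4.04 (adjusted p 2.81e-08), ARI2 by 3.60 and PBEF1 by 3.39. A solute carrier family 11 gene was at least 21.2-fold and gene model 609 at least 5.06-fold higher. Lower in TCO liver were TKTL2 (-3.16), beta B3-crystallin (-2.56), a G protein-activated potassium channel gene (at least 9.84-fold), matrix Gla protein (at least 6.02-fold), synaptogyrin 2-like (at least 5.33-fold) and zinc finger CCHC domain-containing protein 10 (at least 4.76-fold). The venom-type lectin nattectin gave -8.05 ± 2.03 (adjusted p 0.0217), with 1 of 2 TCO arrays measured at each temperature. Oestrogen-responsive liver genes (6) went up in TCO by a median of 1.02 (adjusted p 0.0160; adjusted p 0.729 with an estimated correlation). Of these 1 rose, CTSD at 1.12, 5 did not pass and 3 passed adjusted over the list alone. This call ended with slide as a block (adjusted p 0.114), without both arrays high in pancreatic genes and without each of 4 single arrays in turn. Cell cycle and DNA replication genes (16) went down by a median of -0.48 (adjusted p 0.00644; adjusted p 0.577 with an estimated correlation). Of these 5 fell and 8 passed adjusted over the list alone.

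In kidney, gene model 609 was at least 52.4-fold higher in TCO and lipase member H at least 11.1-fold. The pentraxin gene APCS was higher by 5.09 and profilin-2 by 4.01. XIP (adjusted p 0.00156) and API5 (adjusted p 0.000394) were well above background in TCO on all 4 arrays and in BORN on 0 of 4. Lower in TCO were CLCB (-3.45, 1 of 2 TCO arrays measured at each temperature), the lipid droplet protein gene M6PBP (-3.07), BCA3 (at least 5.02-fold), the same potassium channel gene (at least 4.95-fold), a choline transporter homolog (at least 4.27-fold) and the germ cell RNA helicase Vasa (at least 3.84-fold). Glycolysis and gluconeogenesis genes (27) went up by a median of 0.27 (adjusted p 0.000111; adjusted p 0.0650 with an estimated correlation). Of these 2 rose (ENO3 at 1.44 and PFKFB4 at 1.47) and 5 passed adjusted over the list alone. This call and the next 2 ended with symbols of the gene name column alone. Xenobiotic metabolism genes (8) went up by a median of 0.53 (adjusted p 0.00187; adjusted p 0.0646 with an estimated correlation). Of these 3 rose (CYP1A at 1.26, FMO5 at 1.61 and EPHX1 at 0.79) and 4 passed adjusted over the list alone. Interferon-stimulated genes (23) had a median of 0.18 (adjusted p 0.0347; adjusted p 0.733 with an estimated correlation), and 2 rose, among them IFI30 at 1.45. This call ended with the replicate number or slide as a block (adjusted p 0.246 for slide) and without each of 4 single arrays in turn.

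In gill, gene model 609 was at least 38.8-fold higher in TCO, FAST kinase domain-containing protein 1 at least 19.9-fold, XIP at least 14.2-fold, PQ loop repeat-containing protein 3 at least 13.2-fold and the mitochondrial 39S ribosomal protein L14 at least 8.22-fold. Lipase member H was higher by 3.89 (1 of 2 arrays measured in BORN at 5 °C). Lower were the proteasome gene PSMB7 (at least 8.71-fold), BCA3 (at least 5.46-fold), the chaperone gene hsp90 (at least 5.30-fold), a GPI anchor attachment protein gene (at least 5.00-fold), synaptogyrin 2-like (-2.59) and zinc finger CCHC domain-containing protein 10 (-2.48). Cartilage, bone and connective tissue markers (15) went down by a median of -0.50 (adjusted p 3.75e-05; adjusted p 0.0840 with an estimated correlation). Of these 3 fell (COL2A1 at -0.81, COL5A2 at -0.80 and COL1A2 at -0.77) and 6 passed adjusted over the list alone. Skeletal muscle genes (14) went down by a median of -0.91 (adjusted p 0.000511; adjusted p 0.410 with an estimated correlation). Of these 1 fell, TNNI2 at -1.58. The call ended without the BORN 5 °C replicate 1 and with slide as a block, which sets the same array aside. None of the strain list calls passed with an estimated correlation once adjusted (0 in each tissue). With fry's directional test, the liver calls of cell cycle (adjusted p 0.00961) and oestrogen-responsive genes (0.0260) passed. So did those of glycolysis (0.00167) and xenobiotic metabolism (0.000615) in kidney and of cartilage markers (0.00067) in gill. The other strain list calls did not pass with fry.

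**Figure D3:**
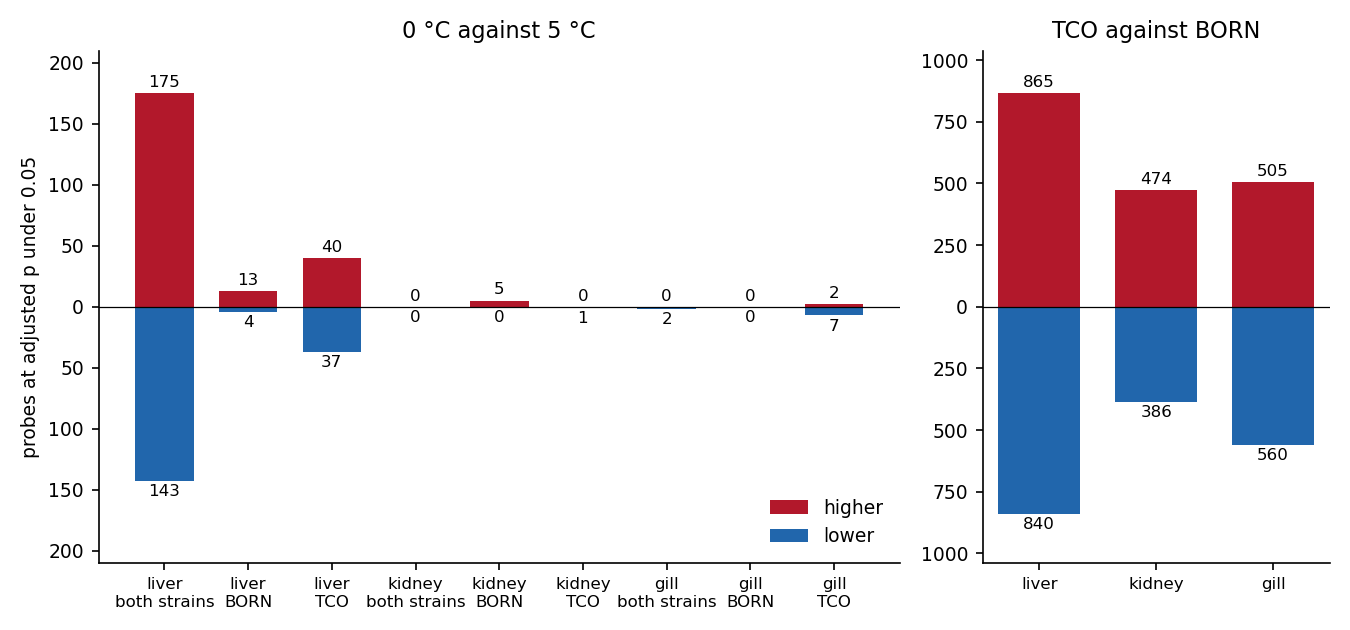
Number of probes past the threshold (limma, adjusted p under 0.05), higher above the axis and lower below it, for the temperature comparisons and the strain differences in each tissue. Temperature gave 318 probes in liver, 0 in kidney and 2 in gill, and strain gave 1705, 860 and 1065.

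The authors' deposited table for each tissue and strain allowed a probe by probe comparison. Together, the authors' deposited table set lists 66 probes with fold changes of at least 2, 44 higher and 22 lower at 0 °C, and all 66 had the same direction in the fit made here. Both come from the same series of arrays, so the shared direction is no independent check. Of those in the authors' deposited table, 29 passed the threshold here: 4 of 22 for BORN liver, 23 of 29 for TCO liver, 1 of 4 for BORN kidney, 1 of 4 for TCO kidney, 0 of 6 for BORN gill and 0 of 1 for TCO gill. Carbonyl reductase 1, named CBR1/20bHSD in the authors' deposited table, has a log2 change of -3.52 in TCO kidney and -3.02 in TCO liver there. HMOX1 stands at 1.93 and FGF1, the gene of heparin-binding growth factor 1, at 1.78 in the authors' deposited table for TCO liver, against 2.45 and 3.28 here, the second with 1 of 2 arrays measured at 5 °C. In the authors' deposited table for BORN liver, MAT2A stands at -1.85, MS4A15 at 1.51 and SOCS2, a suppressor of cytokine signalling, at 1.15, with -2.37, 1.87 and 1.94 here, the last with 1 of 2 arrays measured at 5 °C. UBE2A, at 1.46 in the authors' deposited table, has only the bound given above. Muscle genes lead the authors' deposited table for BORN kidney, with TPM1 at 2.07 and MYL2 at 1.98, and MB stands at 2.06 in that for BORN gill. Among probes measured in both groups, the median fold size was smaller in the authors' deposited table than here, at 2.24 against 2.99 in BORN liver (17 of 22 probes) and 2.37 against 3.48 in TCO liver (26 of 29).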

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

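The test of the skeletal muscle list between strains was chosen only after the result was seen.

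The change between 0 °C and 5 °C in liver differed between the strains for 1 probe, the unnamed A_05_P437487, by the interaction test (adjusted p 0.00446). In TCO its mean level went from -2.69 ± 0.06 (SD, 2 arrays) at 5 °C to -4.60 ± 0.13 at 0 °C, with 2 and 1 of 2 arrays well above background. In BORN 0 of 4 arrays were, so the fitted difference of -2.77 (TCO minus BORN) rests on values below background and is not a measured size.

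The skeletal muscle list differed between the strains in its change at 0 °C, by a median of -1.73 for TCO minus BORN in kidney and of -1.28 in gill. In gill the test had p 0.000462 at the preset correlation, p = 0.0532 with an estimated correlation and fry p 0.0156, and in liver 7 genes gave a median of 0.37 (p 0.199). Skeletal muscle tissue that entered the BORN pools at 0 °C is a candidate explanation, since it would raise many of its abundant genes at once. The median change of the list in BORN, 1.75 in kidney and 0.71 in gill, is the pattern to be explained and no separate support. Leaving out 1 array at a time gave medians of 1.64 to 2.01 in BORN kidney and 0.47 (without the dim 5 °C replicate 2) to 0.99 in BORN gill, whereas the TCO medians ran from -0.66 to 0.55 in kidney, on both sides of 0, and from -0.84 to -0.29 in gill. The list's probe of TPM1, whose level stood at the 73.6th percentile of kidney probes, gave -0.10 and TNNI2 gave -0.01 in BORN kidney. TTN gave -0.12 and ENO3 0.01 there. Not every gene of the list rose, although another TPM1 probe did. In BORN gill the size of the rise differed widely between genes. MB, MYH and MYBPC1 gave 2.30, 2.08 and 2.07, whereas MYLPF, PVALB, TTN and TPM1 gave 0.10, 0.13, 0.14 and 0.02. In liver TPM1 stood at the 83.4th percentile, so its level need not come from muscle. The flat value of TPM1 therefore does not weigh against muscle in the pools, but this does not cover MYLPF and PVALB in gill. A response of the fish to cold that differs between the strains, or between the sexes, stays open and untested, and 14 of the 33 genes of the list were tested in kidney and in gill, ENO3 being also in the glycolysis list.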

How the results depend on the processing

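The alternatives chosen only after the results were seen are those without both dim arrays, without both liver arrays high in pancreatic genes, with the 75th percentile over all probes, and with symbols of the gene name column alone. Of 187 named genes past the threshold, 163 kept their direction and their side of the threshold under quantile normalisation, 89 with normexp, 136 with the replicate block, 136 with the slide block, 172 without both dim arrays and 52 under these and every single array left out, and 0 changed sign in any of them. For genes picked by size of change, the arrays compared did not overlap within a strain or temperature. Leaving out 1 array could therefore not turn their sign. Of 241 alternative counts of probes or lists, with single arrays left out not included, 127 stayed within 1.5 times the main count and 114 did not. All 66 probes of the authors' tables kept their direction under quantile normalisation and normexp. Normexp moved the median of all probes by -0.12 in liver, -0.17 in kidney and -0.26 in gill for both strains together, and by -0.50 in BORN gill, and other scalings moved it by less than 0.1. Where limma gave 0 probes under an alternative, between 177 and 5987 had an unadjusted p under 0.05. The cause of the changes below was not tested, except where a setting tests other probes or fewer arrays. In gill the BORN 5 °C replicate 1 was the only array on its slide. The slide block there leaves the dim array as the 5 °C side of BORN. The gill counts with the slide block that involve BORN are therefore no separate check from leaving that replicate out.

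Counts for both strains together were 318 in liver, 0 in kidney and 2 in gill. In liver they became 34 with normexp, 141 with the replicate block, 766 with the slide block, 784 without both dim arrays, 165 without both arrays high in pancreatic genes, 39 with no filter on dim probes, 189 with a stricter filter and 0 with the arrays of the tissue alone. In kidney they became 2 with quantile normalisation, 1 with the slide block, 4 without both dim arrays and 144 at an unadjusted p with a 2-fold change. In gill they became 11 (7 higher and 4 lower, against 0 and 2) with quantile normalisation, 1 with normexp, 1 with the replicate block, 3380 with the slide block, 9 (1 higher and 8 lower) with the 75th percentile over all probes, 0 without both dim arrays, 6 with no filter, 0 with a stricter filter, 1 with the arrays of the tissue alone, 0 with 1 probe per gene and 450 at an unadjusted p with a 2-fold change.

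In BORN liver the count of 17 became 128 with quantile normalisation, 2 (1 higher and 1 lower, against 13 and 4) with normexp, 5 with the replicate block, 243 with the slide block, 259 without both dim arrays, 35 without both arrays high in pancreatic genes, 1 with no filter, 2 with a stricter filter, 0 with the arrays of the tissue alone and 702 at an unadjusted p with a 2-fold change. In TCO liver 77 became 5 with normexp, 18 with the replicate block, 122 with the slide block, 137 without both dim arrays, 5 with no filter, 26 with a stricter filter, 0 with the tissue alone and 534 unadjusted with a 2-fold change. In BORN kidney 5 became 3 with normexp, 8 without both dim arrays, 0 with a stricter filter, 0 with the tissue alone and 241 unadjusted with a 2-fold change. In TCO kidney 1 became 2 with the replicate block, 0 with the slide block, 4 without both dim arrays, 0 with a stricter filter, 0 with 1 probe per gene and 436 unadjusted with a 2-fold change. In BORN gill 0 became 35 with quantile normalisation, 10189 (395 higher and 9794 lower) with normexp, 4 with the replicate block, 5535 with the slide block, 2069 with no filter and 2086 unadjusted with a 2-fold change. In TCO gill 9 became 1 (1 higher, against 2 higher and 7 lower) with normexp, 1 with the replicate block, 0 with the slide block, 5 with no filter, 0 with a stricter filter, 0 with the tissue alone, 5 with 1 probe per gene and 390 unadjusted with a 2-fold change.

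The difference of the cold effect between strains in liver (1 probe) became 17 (5 higher and 12 lower, against 0 and 1) with quantile normalisation, 0 with normexp, 4 with the replicate block, 6 with the slide block, 3 without both dim arrays, 3 without both arrays high in pancreatic genes, 0 with no filter, 0 with a stricter filter, 0 with the tissue alone and 730 unadjusted with a 2-fold change. In kidney 0 became 1 with normexp, 1 with the 75th percentile over all probes, 5 without both dim arrays and 430 unadjusted with a 2-fold change, and in gill 0 became 3 with quantile normalisation, 1 with normexp, 2410 with the slide block and 1390 unadjusted with a 2-fold change. The strain difference in liver (1705) became 446 with normexp, 787 with no filter, 1002 with a stricter filter, 631 with the tissue alone and 987 unadjusted with a 2-fold change. In kidney (860) it became 309 (219 higher and 90 lower) with the slide block, 524 with no filter and 462 with a stricter filter, and in gill (1065) 4139 with the slide block, 633 with a stricter filter and 527 with the tissue alone. Between liver and kidney 0 became 1 with a stricter filter and 156 unadjusted with a 2-fold change. Between liver and gill 0 became 1 with quantile normalisation, 1 with normexp, 186 with the slide block and 236 unadjusted, and between kidney and gill 0 became 117 unadjusted with a 2-fold change. Lists past the threshold in liver (6) became 1 with normexp, 3 with no filter, 0 with a correlation estimated per list, 0 with symbols of the gene name column alone and 3 without both dim arrays. In kidney (5) they became 3 with no filter, 0 with an estimated correlation and 0 with symbols of the gene name column alone, and in gill (2) 1 with no filter, 0 with an estimated correlation, 1 with symbols of the gene name column alone and 1 without both dim arrays.

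Leaving out 1 array at a time, where the lone array of a group is assumed to vary like the other groups, gave 92 to 473 probes for both strains in liver, 0 to 4 in kidney and 0 to 3289 in gill. It gave 14 to 160 in BORN liver, 13 to 198 in TCO liver, 0 to 11 in BORN kidney, 1 to 16 in TCO kidney, 0 to 5550 in BORN gill and 0 to 9 in TCO gill. The difference between strains ranged over 0 to 58 in liver, 0 to 2 in kidney and 0 to 2158 in gill, and the strain difference over 1077 to 1610, 391 to 798 and 471 to 3932. Between tissues the ranges were 0 to 15 for liver and kidney, 0 to 266 for liver and gill and 0 to 12 for kidney and gill. Lists ranged over 0 to 12 in liver, 3 to 6 in kidney and 1 to 4 in gill.

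The deviations of 0 °C and 5 °C arrays of the same replicate number correlated at r = -0.0767 to 0.289 across probes. In liver and kidney such arrays of a strain shared a slide, which the slide block covers. The labels do not say that a number marks the same fish, and the replicate block gave the counts above.

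The 8 arrays of a tissue were split into 4 and 4 in 35 ways, fitted with the other of strain and temperature as a covariate where the split allows it. For the strain difference only the real split gave as many probes in liver (1662, highest other split 147, that of temperature), kidney (923, highest other 13) and gill (990, highest other 50). This is 1 of 35 splits in each tissue, the smallest share these splits can give, so chance is not excluded. The splits also treat the arrays as independent, although the labels do not say whether the pools of a group held different fish. For the cold effect in liver 2 of the 35 splits gave as many, the real one (283 probes) and the strain split (1386), which was fitted without a strain term and shows a structure of the samples by strain. Whether the real split stands alone there depends on whether the strain split is counted, since of the 34 splits with the covariate only the real one gave as many, with 248 in the next. In gill chance cannot be excluded, since 9 splits gave at least the 1 probe of the real one (highest other 875, that of strain). In kidney the real count was 0, so the splits decide nothing (highest other 940, that of strain).

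The dim arrays were weighed as a cause of the single-strain counts. In TCO kidney quantile normalisation, which gives all arrays the same distribution, left 1 probe, as many as before. The probe of the main fit was carbonyl reductase 1 at -6.02, a change that rescaling the arrays could hardly remove. The dim array is therefore not excluded as an influence on this count. In BORN gill it gave 35 probes where the main count was 0, so quantile normalisation cannot weigh the dim array there. Of the fits above with a single 5 °C array in BORN gill, only the one with the dim array gave probes past the threshold. Those calls went with that array, and they do not show an effect of temperature in BORN gill. Signal over background limits all of this, since no more than 52.2% of probes were well above background on any array.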

Other observations

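The strain tests of the lists and the counts without 2 liver arrays were chosen only after the results were seen. The same holds for the alternatives listed above as chosen afterwards. These include symbols of the gene name column alone and the fits without both dim arrays. No other test reported in this part was chosen only after its result was seen.

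Genes of the exocrine pancreas, a tissue that lies close to other organs in the body cavity of trout, were far higher on 2 of the 8 liver arrays. On the BORN 5 °C replicate 1 the digestive enzyme genes CELA1, CEL, CTRB1 and CPA1 lay 4.37, 4.40, 4.22 and 4.66 above their liver means on the log2 scale, and on the TCO 0 °C replicate 1 they lay 5.12, 4.74, 4.91 and 4.27 above. CTRL lay 3.53 and 3.40 above, whereas a trypsinogen-like probe (PRSS1) lay at -0.08 and 0.36. Because 1 of these arrays belongs to each temperature, the median change of the 6 genes was -3.24 in BORN and 3.23 in TCO, with 0 past the threshold in either strain and 5 adjusted over the list alone in BORN. Over both strains 0 passed, and PRSS1 gave 0.58. In kidney 6 genes of this list and in gill 4 gave medians between -0.16 and 0.28 in each strain.

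Some further lists differed between the strains at the preset correlation. In kidney, proteasome and ubiquitin genes (33) were lower in TCO by a median of -0.19 (adjusted p 0.0212; adjusted p 0.733 with an estimated correlation; 1 rose, 2 fell) and cell cycle and DNA replication genes (18) by a median of -0.28 (adjusted p 0.0324; adjusted p 0.733 with an estimated correlation; 0 past the threshold). Both calls ended with slide as a block (adjusted p 0.246 and 0.330) and without each of 3 single arrays in turn, and that of the cell cycle also with symbols of the gene name column alone. In gill 68 ribosomal protein genes had a median of -0.18 (adjusted p 0.0390; adjusted p 0.932 with an estimated correlation; 1 rose). This call held under 8 of 19 alternatives and its direction turned under 2. It ended with quantile normalisation, with normexp and without the dim BORN 5 °C array, on which the list lay 0.91 above the gill mean.

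Carbonyl reductase 1 had high levels on all 6 TCO arrays at 5 °C and low levels on the 6 TCO arrays at 0 °C, in 3 tissues. A hypothesis is that the TCO pools at 5 °C and at 0 °C held fish that differed in this gene whatever the temperature, which the same pools would carry into every tissue. If pools of the same number held the same fish in each tissue, the difference between the replicates of a group would correlate across tissues over the 2101 probes that differ between strains. Over 12 pairs of tissues the median of these correlations was 0.226 (0.0631 to 0.301), and 9 lay above 0.2, so the pools may share fish across tissues. The replicate 1 arrays of TCO liver and kidney shared a slide, as did the replicate 2 arrays of TCO kidney and gill. The correlations therefore cannot tell shared fish from shared slides. They also do not show whether the 5 °C and 0 °C pools differed in carbonyl reductase 1. The other probes gave a median of 0.163, and the strain probes gave the higher value in 10 of the 12 pairs, so the other probes correlate too but less, and a fall of the transcript in TCO at 0 °C remains open.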
